A study of Drosophila melanogaster with 40 samples.

How the data were processed

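RNA of whole flies of Drosophila melanogaster was measured by 3' end sequencing in 40 libraries, which per the labels were made with a Lexogen Quant 3' mRNA-Seq V2 kit. Only read 1 was used by the authors. The deposited values were raw counts per gene, 1 column per library, with no normalization, and the submitters' notes named STAR 2.7.5a and the dm6 genome build. The counting tool, its annotation, its strand setting and any use of molecular identifiers were not stated. Counts were used as deposited. The table held 17609 genes, of which 17596 were matched to a symbol and 1824 had no count in any library. Library totals ran from 11714961 to 48747409 counts, and floors, which are 3 counts, cover counting error only.

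Genotype, age, behaviour, hour and batch of each library came from the labels. Each of the 40 conditions had 1 library, with controls at 4 h only. The spread was therefore taken from an additive model with terms for the 4 combinations of genotype and age, for the state (control, or hour after heat shock) and for non-climbers in young and in old wild-type flies, with 28 residual degrees of freedom. It assumes that hours act alike in all 4 combinations. The 5 batches followed genotype, age and hour, so batch was not a term of this model and entered as an alternative.

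Genes were tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood (robust fit, TMM factors, filterByExpr) and Benjamini-Hochberg adjustment within each comparison, with a threshold of 0.05. Of the genes, 11449 passed the count filter, and the common dispersion was 0.0681. Log2 fold changes are fitted values with their standard errors. Differences in time course were tested as slopes on the log2 of the hour plus 1, in 24 climber libraries (11467 genes, 12 residual degrees of freedom) and in 24 heat-shocked wild-type libraries (11330 genes, 13 residual degrees of freedom). Levels are counts per library scaled by TMM, as CPM, and log2 CPM used a prior count of 2.

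The 27 gene lists were written from general knowledge of fly genes. They were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. The heat shock index was the mean log2 CPM of 16 inducible heat shock genes. The levels of Ilp2, Ilp3 and Ilp5 were summed per library and compared by a two-sided permutation test with 100000 resamples.

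Genes were named by a fixed rule. It took up to 6 genes with the largest rise and 6 with the largest fall per comparison, among those past the threshold with an average log2 CPM of at least 3 and the same sign in every matched pair of libraries. It added up to 3 passing members of each list, 5 genes per interaction or slope, the insulin-like peptides of the ablated cells and the heat shock genes, and the 3 genes with the smallest p where none passed. The text prints a subset of these, and the table of named genes holds all. The comparisons, the lists, the naming rule and the first set of alternatives were fixed before the data were examined.

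The alternatives were DESeq2 1.42.0 (Wald test, likelihood ratio test over hours), RLE factors, TMM factors without heat shock genes, other count filters, batch as a covariate, limma-voom with batch as a random block, smaller sets of libraries, a slope on hours, and leaving out each hour or control in turn. Further alternatives, added after the data were seen, left out ablated young libraries or added a library set with 2 levels, taken from the first principal component of 931 transcripts without protein coding (26.9% of their variance). A change of sign where neither value passed was not counted as a reversal. Other splits of the libraries were counted with limma-voom, with the real split recounted the same way. A split and its mirror were taken once, which gave 32 splits for behaviour within an age, 64 for genotype and for age in ablated flies, and 100 drawn with a fixed seed elsewhere.

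The fit was tested on simulated data, drawn from the fitted model with the tested effect removed and then set in 200 genes with an average log2 CPM of at least 3, and fitted without the robust option. For heat at 4 h it recovered 97 of them at a fold of 1.5, 186 at a fold of 2 and 194 at a fold of 3. For behaviour it recovered 179, 194 and 198, and for age in wild type 152, 192 and 198. None had the wrong sign, and 4 to 16 other genes were called. The simulated counts followed the additive model without batch, library set or exchanged labels. These figures therefore do not cover such structure in the real libraries. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Libraries were checked for duplicated columns, and the closest pair had a Pearson correlation of 0.9803 in log2 CPM without being identical. No library was left out of the comparisons.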

Results

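RNA from whole flies of Drosophila melanogaster was sequenced in 40 libraries made with a kit that reads the 3' end of messenger RNA. The flies carried intact or ablated insulin-producing cells, the brain neurons that secrete insulin-like peptides. They were young or old, and they were collected at 0, 1, 2, 4, 6 or 8 h after a heat shock. Heat-shocked wild-type flies were split by a climbing test into climbers and non-climbers, ablated flies were represented by climbers only, and each of the 4 combinations of genotype and age had 1 control library at 4 h without heat shock. Wild-type young and wild-type old flies gave 13 libraries each, and ablated young and ablated old flies gave 7 each. Total counts per library ran from 11714961 to 48747409. Each condition had 1 library, so no condition was replicated. The p-values measure effects against the scatter left around additive terms for genotype and age, hour and behaviour over 28 residual degrees of freedom.

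The transcripts of the ablated cells were examined first, since they check the genotype labels. The summed level of Ilp2, Ilp3 and Ilp5 was 2.26 ± 0.787 CPM (SD, n = 26) in wild-type libraries and 0.220 ± 0.305 (SD, n = 14) in ablated libraries. A permutation test of this difference gave p = 1e-05, the smallest value that 100000 resamples can give. Ilp2 had 5 to 40 counts in each of the 26 wild-type libraries and 7 counts in all 14 ablated libraries together. Ilp3 kept 47 counts in 7 ablated libraries, and Ilp5 kept 17 counts in 3 ablated libraries. Of the Ilp3 counts, 20 were in ablated old 1 h (1.01 CPM) and 14 in ablated old 6 h (0.727 CPM). Both levels lay above the wild-type mean of 0.461 CPM, so Ilp3 alone did not check the label of these libraries. These floors and counts cover counting error only.

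The inducible heat shock genes checked the treatment labels. Their mean log2 level, taken over 16 genes, lay 3.45 to 4.51 above the control at 0 h in wild-type flies and 4.63 above it in old ablated flies. It then declined to between 1.81 and 2.32 above the control at 8 h in the same series, and in young ablated flies it went from 3.16 to 0.0875. The library labelled ablated young control had an index of 5.66, above the 3 other controls, which lay between 3.21 and 4.72. The library labelled ablated young 6 h had 3.53, inside the range of those controls and 2.13 below the labelled control of its stratum. Both libraries were used as labelled, and counts or values without them are given for some of the results. The libraries also fell into 2 sets in their transcripts without protein coding, with all 26 wild-type libraries and the ablated young 0 h and 1 h libraries in the first set and the 12 other ablated libraries in the second. Genotype was therefore nearly inseparable from this split.

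**Figure D1:**
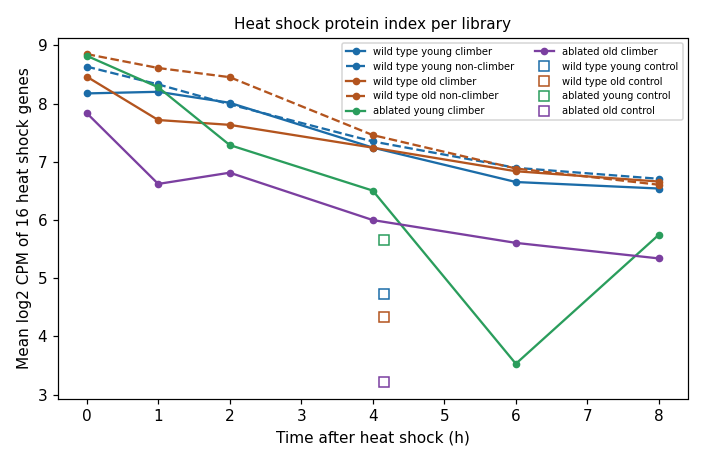
Mean log2 CPM of 16 inducible heat shock genes against the time after heat shock in hours, with 1 point per library, lines joining a series and open squares for the 4 controls of 4 h. The library labelled ablated young control lies at 5.66, and the library labelled ablated young 6 h at 3.53.

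**Figure D2:**
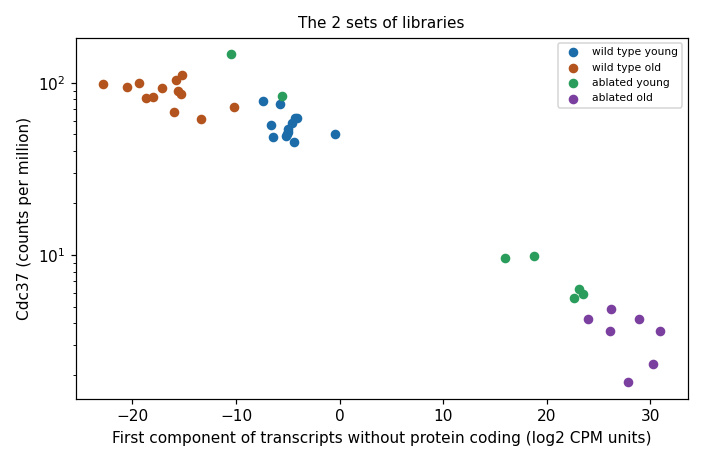
Cdc37 in CPM on a log axis against the first component of the transcripts without protein coding in log2 units, with 1 point per library coloured by genotype and age. The 28 libraries of the first set and the 12 of the second are 16.4 apart on the component.

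What heat shock left at 4 h was asked against the controls of the same hour, with 6 heat-shocked and 4 control libraries, and values are log2 fold changes with standard errors. Small heat shock genes and members of the Hsp70 family rose strongly, with Hsp23 (3.76 ± 0.75), Hsp68 (3.62 ± 0.90), Hsp70Ab (3.53 ± 0.84), Hsp70Ba (5.08 ± 1.12) and Hsp67Bc (2.65 ± 0.64), with smaller rises of Hsp26 (0.96 ± 0.16) and Hsp83 (0.37 ± 0.08). The adjusted p of these 7 genes was at most 0.0483 (edgeR quasi-likelihood, Benjamini-Hochberg). The Hsp70 copies have nearly identical sequences and share reads, so values of single copies were uncertain, and Hsp70Aa (2.19 ± 0.61), Hsp70Bb (3.37 ± 0.87) and Hsp70Bc (2.18 ± 0.74) did not pass. Of the 30 named values of this contrast, 5 that had not passed did so without the library labelled ablated young control, while 3 lost their call. When each other hour and each control was left out in turn, 9 fits, the call was kept in 9 for Hsp26, in 5 for Hsp23, Hsp70Ba and Hsp83, in 3 for Hsp70Ab and in 2 for Hsp68 and Hsp67Bc. All but Hsp26 lost it without the 2 h libraries, where Hsp68 stood at 3.66, Hsp70Ab at 3.58 and Hsp67Bc at 2.73, or without the wild-type old control, at 3.12, 3.44 and 2.29. In the inducible heat shock list 8 of 16 measured members rose and none fell, 15 adjusted over the list alone (camera adjusted p 6.3e-24 and 0.0077). Wherever a list is followed by a pair of adjusted p from camera, the first used the preset correlation between genes and the second the correlation estimated from the data. Hsp22 had no count in any library, and Hsp27 was absent from the table and was not analysed here.

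Single glutathione transferase and P450 genes rose at 4 h. The glutathione transferases GstE7 (2.20 ± 0.33), GstE3 (1.63 ± 0.27) and GstE8 (0.80 ± 0.15) rose, as did the P450 genes Cyp12d1-p (1.43 ± 0.28) and Cyp12a5 (0.91 ± 0.22). Of the 9 fits that left out another hour or a control, the call was kept in 9 for GstE7 and GstE3, 8 for GstE8, 7 for Cyp12d1-p and 3 for Cyp12a5. In the glutathione transferase list 3 of 25 members rose, 8 up and 1 down adjusted over the list alone (camera adjusted p 3.56e-06 and 0.033), while the P450 list, with 2 of 30 higher and 4 up and 0 down adjusted over the list alone, did not pass (camera adjusted p 0.346 and 0.756). Transcripts assigned to the mitochondrial genome rose in 8 of 36 cases, among them mt:tRNA:Gln-TTG (2.41 ± 0.57) and mt:tRNA:Val-TAC (2.09 ± 0.45), and 21 rose and 1 fell adjusted over the list alone (camera adjusted p 4.39e-20 and 0.0631). Both of these tRNA genes kept their call in only 3 of those 9 fits. The pseudogene CR43687 (FlyBase FBgn0263770, chromosome 2R, 18401846 to 18402297 in the dm6 assembly) rose by 4.54 ± 0.70. It is uncertain which copy its reads came from.

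Single genes of blood cells and of digestion were lower at 4 h. The haemocyte genes Hml (-1.30 ± 0.29) and PPO2 (-1.13 ± 0.27) fell, and PPO2 encodes a prophenoloxidase of crystal cells. The gut protease Jon65Aiv (-1.24 ± 0.30), the maltase Mal-A6 (-0.97 ± 0.24), CG5390 (-0.83 ± 0.20), Spt (-0.69 ± 0.17) and CG3902 (-0.64 ± 0.15) also fell, each with an adjusted p of at most 0.0443 (edgeR quasi-likelihood, Benjamini-Hochberg). The haemocyte list had 2 of 13 members lower, 5 adjusted over the list alone (camera adjusted p 0.000952 and 0.0631). The list of sugar storage and digestion had 1 of 17 lower, 6 adjusted over the list alone (camera adjusted p 1.25e-06 and 0.273), and trypsins and jonahs 1 of 27, 4 adjusted over the list alone (camera adjusted p 0.000139 and 0.483), so these 3 lists did not pass with the estimated correlation. Of the 9 fits that left out an hour or a control, Hml kept its call in 5, PPO2 and CG3902 in 4, and Jon65Aiv, Mal-A6, CG5390 and Spt in 3. The values of Ilp2 (0.46 ± 0.83), Ilp3 (0.21 ± 1.49) and Ilp5 (-0.59 ± 0.96) did not pass, and neither did those of DnaJ-1 (0.59 ± 0.15) and stv (1.78 ± 0.45). Without the libraries labelled ablated young control and ablated young 6 h, 5 named values of this contrast gained a call and 2 lost it. Values that did not pass at 4 h thus rest in part on libraries in doubt.

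In all, 88 genes passed at 4 h, 71 higher and 17 lower, and the count leaned on the controls. Without the wild-type young control 5 genes passed, without the wild-type old control 7, without the ablated old control 13, and without the library labelled ablated young control 277. Leaving out an hour gave 56 without 0 h, 57 without 1 h, 24 without 2 h, 202 without 6 h and 174 without 8 h, and batch as a covariate gave 226. The excess of higher genes was no firmer, at 80.7% in the 88 genes but 59.3% of those 226, 54.6% of 379 without the 2 doubtful libraries, 69.8% of 169 in the 10 libraries of 4 h alone, and 47.8% in limma-voom, with 55 higher and 60 lower.

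The controls were collected only at 4 h, so the contrasts at the other hours set heat shock and hour of collection together against them. At 0 h 443 genes passed, 198 higher and 245 lower, and the counts were 234 at 1 h, 157 at 2 h, 13 at 6 h and 81 at 8 h. The share of higher genes at 0 h, 44.7%, became 59.6% with batch as a covariate (294 higher and 199 lower), so the prevailing direction was not settled. The inducible heat shock list stood highest at 0 h, with a median of 3.57 and 14 of 16 members higher (camera adjusted p 4.96e-39 and 0.00032), and its median was 3.05 at 1 h and 2.83 at 2 h. Constitutive chaperones rose early, 9 of 20 at 0 h and 3 at 1 h, with 15 up and 1 down at 0 h adjusted over the list alone (camera adjusted p 4.53e-09 and 0.000834). Antimicrobial peptides were lower at 0 h, 17 of 33 members and 30 adjusted over the list alone, with a median of -1.53 (camera adjusted p 8.99e-23 and 0.0958). The fall covered 3 members at 1 h and 4 at 2 h, and none passed at 4 h. Genes for sugar storage and digestion fell in 3 of 17 cases at 1 h, 6 adjusted over the list alone (camera adjusted p 1.41e-05 and 0.248). Of the other lists, lipid storage and synthesis had 2 of 19 members lower at 0 h, 5 adjusted over the list alone, and the male list had none of 7 past the threshold.

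Without the library labelled ablated young control, and with that labelled ablated young 6 h also set aside, 297 genes passed at 2 h, 379 at 4 h, 432 at 6 h and 527 at 8 h. At 1 h the count was 128 without the wild-type young control, 144 without the ablated old control and 150 without the 2 h libraries. At 2 h it was 84 without the wild-type young control, 78 without the ablated old control and 243 without the labelled ablated young control, and at 0 h it was 294 without the ablated old control. At 6 h it was 0 without the wild-type young, wild-type old or ablated old control or the 1 h or 2 h libraries, 1 without the 0 h or 4 h libraries, 29 without the 8 h libraries and 107 without the labelled ablated young control. At 8 h it was 0 without the wild-type young or ablated old control, 10 without the wild-type old control and 465 without the labelled ablated young control. It was 52 there without the 0 h libraries, 40 without 1 h, 27 without 2 h and 183 without 6 h. A test of any difference among the 6 hours gave 997 genes, 495 without the 0 h libraries and 384 with batch as a covariate.

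How transcripts moved between 0 h and 8 h was asked in 6 series, with 6 libraries at each hour. Vitelline membrane genes, which are transcribed in the follicle cells around growing eggs, fell strongly, with Vm32E (-5.26 ± 0.83), Vm26Ac (-4.12 ± 0.76), Vm34Ca (-3.64 ± 0.55), Vm26Aa (-3.45 ± 0.44) and psd (-3.78 ± 0.70). The eggshell-associated genes CG14309 (-4.01 ± 0.72) and Fcp3C (-3.61 ± 0.71) were lower as well, and each of these 7 fell in all 6 series. Vm32E (FlyBase FBgn0014076, chromosome 2L, 11171167 to 11171665 in dm6) went from 112 to 514 CPM at 0 h down to between 0.926 and 27.5 at 8 h. In the female germline and eggshell list 10 of 24 members were lower, 12 adjusted over the list alone, with a median of -0.73 (camera adjusted p 2.31e-07 and 0.14).

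**Figure D3:**
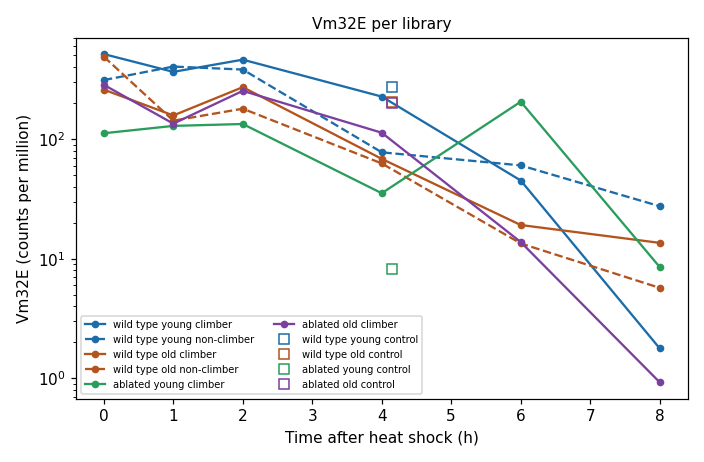
Vm32E in CPM on a log axis against the time after heat shock in hours, with 1 point per library, lines joining a series and open squares for the 4 controls of 4 h. The 0 h libraries lie between 112 and 514, and the 8 h libraries between 0.926 and 27.5.

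Heat shock transcripts fell over the same span. The values were Hsp83 (-1.16 ± 0.07), Hsp26 (-2.03 ± 0.14), DnaJ-1 (-1.85 ± 0.14), Hsp68 (-3.03 ± 0.69), Hsp23 (-2.90 ± 0.58) and stv (-2.12 ± 0.38), with adjusted p of at most 0.00386 (edgeR quasi-likelihood, Benjamini-Hochberg). The Hsp70 copies fell by similar amounts, from Hsp70Aa (-2.34 ± 0.50) and Hsp70Bc (-2.88 ± 0.61) to Hsp70Ab (-3.11 ± 0.66), Hsp70Ba (-3.11 ± 0.65) and Hsp70Bb (-3.55 ± 0.63), and 15 of the 16 members of the inducible list were lower (camera adjusted p 1.53e-18 and 0.0147). Constitutive chaperones followed in 12 of 20 cases, for example Stip1 (-0.42 ± 0.06) (camera adjusted p 2.23e-07 and 0.00641). The early glutathione transferases and P450 also fell, with GstE8 (-1.39 ± 0.13), GstE7 (-1.73 ± 0.27) and Cyp12d1-p (-1.72 ± 0.24).

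Another group of genes was higher at 8 h than at 0 h. Among genes that met the level and sign rule for named genes, the largest increases were those of GstD2 (3.61 ± 0.54), Cyp6a8 (2.82 ± 0.53), mt:tRNA:Met-CAT (2.61 ± 0.36), Fst (2.48 ± 0.47), mat (2.28 ± 0.40) and CG31106 (2.28 ± 0.32), all in the same direction in the 6 series. GstD2 (FlyBase FBgn0010038) encodes a glutathione transferase induced by oxidative damage. P450 genes rose in 11 of 30 cases and fell in 1, for example Cyp4p1 (2.26 ± 0.25) (camera adjusted p 2.31e-07 and 0.0606). Mitochondrial transcripts rose in 15 of 36 cases, for example mt:tRNA:Cys-GCA (2.24 ± 0.24) (camera adjusted p 3.69e-14 and 0.146). Antimicrobial peptides rose in 10 of 33 cases, among them BomT1 (2.11 ± 0.42) (camera adjusted p 3e-08 and 0.405).

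Single genes of several other lists were higher at 8 h. FOXO-activated genes rose in 4 of 9 cases, among them Lip4 (1.78 ± 0.29) and Thor (0.90 ± 0.22) (camera adjusted p 0.00428 and 0.268), and FOXO is the transcription factor that insulin signalling holds out of the nucleus. The insulin-like peptides Ilp8 (1.19 ± 0.20) and Ilp7 (1.504 ± 0.35) rose, whereas Ilp2 (0.24 ± 0.67), Ilp3 (-0.03 ± 0.88) and Ilp5 (-0.83 ± 0.91) did not pass. The damage-response factor Xrp1 (0.98 ± 0.16), the autophagy gene Atg8a (0.67 ± 0.09), the lipid droplet gene Lsd-1 (1.60 ± 0.28), the sugar-responsive factor sug (1.19 ± 0.21), the metallothionein MtnE (1.49 ± 0.27), the protease gene Jon66Cii (3.08 ± 0.75) and the endoplasmic reticulum gene Sil1 (0.99 ± 0.20) rose too. The insulin signalling list had 4 of 20 members higher while its median was -0.10, against the upward direction of its test, which did not pass at 0.64 (camera, Benjamini-Hochberg). In all, 1201 genes passed, 740 higher and 461 lower, and 306 passed with batch as a covariate, where 79.4% were higher against 61.6% without it.

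Whether non-climbers differed from climbers was asked in 12 wild-type pairs of the same age and hour. No gene passed in edgeR quasi-likelihood, where 429 genes had an unadjusted p under 0.05, and none passed in limma-voom, while DESeq2 called 3. The smallest p belonged to CG31928 (-1.33 ± 0.28), CG43134 (-0.31 ± 0.07) and CG9864 (-0.48 ± 0.11), which did not pass at an adjusted p of 0.485 (edgeR quasi-likelihood, Benjamini-Hochberg). CG31928 had the same sign in 10 of 12 pairs, and it was called by DESeq2 and in edgeR without the 0 h libraries, where 1 gene passed. With the pair as a block 2 genes passed, CG13607 (-0.73 ± 0.10) and mt:tRNA:Arg-TCG (0.31 ± 0.05), named here after their values were seen. The other 2 genes of DESeq2, CG46399 and CR46423, had fitted changes of 19.72 ± 3.73 and -12.96 ± 2.39, sizes that come from genes without a count in most libraries.

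Heat shock genes leaned upward in non-climbers without passing. The values were Hsp83 (0.14 ± 0.05), DnaJ-1 (0.25 ± 0.09), stv (0.46 ± 0.25), Hsp26 (0.19 ± 0.09), Hsp68 (0.52 ± 0.44) and Hsp23 (0.11 ± 0.37), and those of the Hsp70 copies lay between Hsp70Aa (0.45 ± 0.33) and Hsp70Bc (0.58 ± 0.39). Hsp70Ab and stv had that sign in 11 of 12 pairs, and Hsp70Ba, Hsp70Bb and Hsp70Bc in 10. The inducible list had a median of 0.35 (camera adjusted p 0.000353 and 0.793), so its call was lost with the estimated correlation. The female germline and eggshell list had a median of -0.15, with 5 of 24 members lower adjusted over the list alone and none over all genes (camera adjusted p 5.08e-06 and 0.712). Ilp2 (0.38 ± 0.44), Ilp3 (0.15 ± 0.62) and Ilp5 (-0.18 ± 0.56) did not pass. By age, no gene passed in young flies (303 at an unadjusted p under 0.05, 2 in DESeq2), in old flies (354, and 1 in DESeq2), or for the difference between ages (244, and 4 in DESeq2), and limma-voom called none in these 3 tests. With the pair as a block 2 genes passed in old flies, again CG13607 (-0.92 ± 0.15) and mt:tRNA:Arg-TCG (0.43 ± 0.07), seen only after the fit, at an adjusted p of 0.0218 (edgeR quasi-likelihood, Benjamini-Hochberg). The smallest p for the difference between ages belonged to Obp56h (2.55 ± 0.65), asRNA:CR32252 (-8.67 ± 2.24) and CG7214 (-8.06 ± 2.14), none of which passed, and the antisense transcript is uncertain because the strand of the counting was not stated.

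What age changed was asked first in wild-type flies, with 13 old and 13 young libraries. Immune effectors were among the increases, with DptA (4.48 ± 0.79), Dro (4.37 ± 0.74), CecA1 (4.21 ± 0.78), AttD (3.99 ± 0.62), Def (3.90 ± 0.60) and BomT2 (1.52 ± 0.21), and 32 of 33 antimicrobial peptide genes rose, with a median of 1.81 (camera adjusted p 3.38e-22 and 0.104). The largest increase among genes above the level minimum was that of CG43920 (FlyBase FBgn0264541, chromosome 2R, 17598845 to 17599253 in dm6), at 5.32 ± 0.91. Signals of damage rose as well, with the cytokine upd3 (2.17 ± 0.35), its feedback inhibitor Socs36E (1.62 ± 0.22), the metalloproteinase Mmp1 (2.23 ± 0.35) and the factor Ets21C (1.96 ± 0.33), and 6 of 12 genes of the JNK and damage list rose (camera adjusted p 3.82e-05 and 0.18). In the Turandot and JAK/STAT list 2 of 12 members rose (camera adjusted p 0.0198 and 0.173). The adjusted p of the genes named here was at most 0.000218 (edgeR quasi-likelihood, Benjamini-Hochberg). Each of them kept its call in 13 of 14 alternative fits, but none kept it with batch as a covariate.

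Several lists had many members lower with age in wild-type flies, though in this comparison no list passed with the estimated correlation. Nuclear genes of oxidative phosphorylation fell in 63 of 71 cases, for example ND-B8 (-3.06 ± 0.25) and SdhA (-0.60 ± 0.07) (camera adjusted p 2.45e-36 and 0.104), and mitochondrial genes fell in 14 of 36 cases, with mt:ATPase6 (-0.87 ± 0.09) among them (camera adjusted p 0.00327 and 0.553). Glycolysis genes fell in 11 of 14 cases, with Ald1 (-0.83 ± 0.08) and Gapdh1 (-0.77 ± 0.09) (camera adjusted p 1.13e-06 and 0.104). Muscle genes fell in 13 of 24 cases, for example Mf (-1.41 ± 0.11), the gene of myofilin (camera adjusted p 1.49e-09 and 0.184). Proteasome genes fell in 18 of 30 cases, for example Prosbeta6 (-0.42 ± 0.07) (camera adjusted p 1.48e-09 and 0.142), and ribosomal protein genes in 43 of 86, for example RpS2 (-0.57 ± 0.08) (camera adjusted p 1.83e-11 and 0.327).

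Most trypsin and jonah genes and a few genes of blood cells were lower with age too. Trypsins and jonahs were lower in 19 of 27 cases, with epsilonTry (-2.66 ± 0.27) and Jon65Aii (-3.32 ± 0.57) (camera adjusted p 3.4e-11 and 0.142), and the lipase gene mag (-3.10 ± 0.43) and the maltase gene Mal-A3 (-1.75 ± 0.27) fell. The prophenoloxidase genes PPO2 (-2.88 ± 0.24) and PPO1 (-2.13 ± 0.27) fell, the only 2 lower of 13 members of the haemocyte list, 2 adjusted over the list alone (camera adjusted p 0.0113 and 0.142), as did CG12057 (-3.38 ± 0.41), Scp1 (-3.27 ± 0.45) and CG18179 (-2.81 ± 0.48), and the constitutive chaperone Hsc70-1 (-1.04 ± 0.14) fell with 5 other members of its list of 20. The yolk protein genes Yp2 (-1.09 ± 0.20) and Yp3 (-1.02 ± 0.20) fell, whereas the germline gene nanos (0.88 ± 0.16) rose. The rhodopsins Rh4 (1.09 ± 0.12) and Rh6 (1.15 ± 0.15), the clock gene vri (0.96 ± 0.15), the P450 Cyp6a13 (1.20 ± 0.16) and the adipokinetic hormone gene Akh (1.05 ± 0.16) rose, and Ilp7 (-1.89 ± 0.34) fell. P450 genes rose in 13 of 30 cases (camera adjusted p 0.000579 and 0.173), and clock genes in 3 of 11 (camera adjusted p 0.0181 and 0.2). Ilp2 (0.03 ± 0.56), Ilp3 (0.52 ± 0.81) and Ilp5 (0.52 ± 0.74) did not pass. Of the heat shock genes Hsp26 (-0.42 ± 0.13) fell, a call lost without the 2 h libraries (-0.39 ± 0.14), and the rest lay between Hsp70Aa (-0.52 ± 0.46) and Hsp70Bb (1.12 ± 0.52) without passing. In all, 2692 genes passed, 1352 higher and 1340 lower (1314 and 1446 with TMM factors without heat shock genes), and 79 passed with batch as a covariate. Of 52 named values of this comparison, 28 lost their call with batch as a covariate. Young and old wild-type libraries shared only batch 2, and that fit also tested more genes.

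The age comparison was repeated in ablated flies, with 7 old and 7 young libraries. Antimicrobial peptides again rose, 24 of 33 genes (camera adjusted p 5.44e-13 and 0.202), among them DptA (4.90 ± 0.82), CecA1 (4.79 ± 0.84), CecA2 (4.32 ± 0.84), Dro (4.35 ± 0.75), AttC (4.30 ± 0.51), AttA (4.01 ± 0.63) and edin (5.16 ± 1.00), and CG43920 (4.58 ± 0.83) and upd3 (1.61 ± 0.35) rose with them. CecA1 and CecA2 are close copies that share reads, so their separate values are uncertain. All 24 measured muscle genes fell, with a median of -2.05 (camera adjusted p 6.02e-23 and 0.0534), for example Mf (-2.76 ± 0.12), Mlp60A (-1.41 ± 0.10) and TpnC4 (-4.81 ± 0.58). Neuronal genes fell in 19 of 21 cases, with the sodium channel para (-3.19 ± 0.21) and the receptor Rdl (-2.52 ± 0.18) (camera adjusted p 6.84e-15 and 0.0534), and photoreceptor genes in 17 of 21, with rdgA (-2.21 ± 0.17) (camera adjusted p 1.01e-09 and 0.0534).

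Most oxidative phosphorylation and glycolysis genes were lower with age in ablated flies as well, where no list passed with the estimated correlation. Oxidative phosphorylation genes fell in 64 of 71 cases, for example COX6B (-1.03 ± 0.07) (camera adjusted p 4.83e-30 and 0.0952), and mt:CoI (-0.62 ± 0.09) fell. Glycolysis fell in 9 of 14 cases with Ald1 (-1.92 ± 0.08) (camera adjusted p 0.000337 and 0.202), and Glyp (-0.62 ± 0.08), the glycogen phosphorylase gene, fell. Ribosomal protein genes split, with 43 of 86 higher and 5 lower, RpL39 (-0.37 ± 0.05) among the lower (camera adjusted p 8.38e-08 and 0.536). The antioxidant list had 10 of 21 members higher, with Fer1HCH (0.64 ± 0.07), and 2 lower, with Sod2 (-0.65 ± 0.07) (camera adjusted p 0.0261 and 0.32). Endoplasmic reticulum stress genes rose in 6 of 19 cases, with Pdi (0.70 ± 0.10) (camera adjusted p 0.0248 and 0.272).

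Single genes with large falls in ablated flies were CG11458 (-8.15 ± 1.09), Acp65Aa (-6.99 ± 1.30), CG7203 (-5.92 ± 1.02), NimC4 (-5.02 ± 0.84), Scp1 (-4.51 ± 0.45), PPO2 (-2.13 ± 0.23) and Hsc70-1 (-1.76 ± 0.14). Acp65Aa encodes a cuticle protein of adults and NimC4 a receptor for dying cells. The insulin receptor gene InR (-1.80 ± 0.29), foxo (-0.95 ± 0.19), the death gene hid (-2.18 ± 0.41) and the clock gene Clk (-1.30 ± 0.25) fell, epsilonTry (-1.58 ± 0.26) fell, and Cyp6w1 (1.41 ± 0.22) and osk (1.09 ± 0.35) rose. The call of Ilp3 (3.37 ± 1.00) as higher rested on few counts and was kept in 4 of 6 fits that left out an hour, being lost without 1 h (2.56 ± 1.07) and without 6 h (2.83 ± 1.14). In the autophagy list 4 of 18 members rose and 3 fell. Ilp2 (-0.54 ± 0.89) and Ilp5 (0.90 ± 1.03), with counts near 0, did not pass. The Hsp70 copies Hsp70Bb (-4.42 ± 0.71), Hsp70Ab (-3.64 ± 0.68) and Hsp70Ba (-1.95 ± 0.69) were lower, but with the library set as a covariate Hsp70Ba stood at 0.01 ± 0.27 and did not pass, while the other 2 did. Hsp70Ba also lost its call without 0, 1, 2 or 8 h, where it lay between -2.05 and -1.27. Hsp70Ab had 607 and 594 CPM in the young ablated climbers of 0 h and 1 h, both of the first set, and 33.9 CPM or less from 2 h on. The other heat shock genes lay between stv (-0.80 ± 0.35) and DnaJ-1 (0.12 ± 0.12) without passing. In all, 4241 genes passed, 1801 higher and 2440 lower (973 with batch as a covariate), and 2111 passed with the library set as a covariate and without the 2 doubtful libraries, 1953 of them called in both with the same sign. Of 51 named values of this comparison, 20 lost their call with batch as a covariate. Among libraries of 2, 4 and 8 h, all in the second set, 752 genes passed, 98 higher and 654 lower.

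Whether age acted differently in the 2 genotypes was tested as an interaction. The smallest adjusted p belonged to CG5065 (-1.75 ± 0.15), eEF1alpha2 (-1.70 ± 0.15), Cngl (-2.19 ± 0.20), Moe (-1.35 ± 0.12) and cpo (-1.80 ± 0.17), each with a lower age effect in ablated flies, with an adjusted p of at most 2.96e-09 (edgeR quasi-likelihood, Benjamini-Hochberg). With the library set as a covariate and without the 2 doubtful libraries, eEF1alpha2, the gene of a translation elongation factor of adult tissues, kept a value of -1.59 ± 0.14 and cpo one of -1.52 ± 0.12. In all, 4162 genes passed, 1779 higher and 2383 lower. That fit called 2597, with 2486 called in both with the same sign, and batch as a covariate left 286.

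What ablation changed was asked in young flies, with 7 ablated and 13 wild-type libraries. The peptide genes of the ablated cells fell, with Ilp2 (-4.93 ± 0.73), Ilp5 (-4.52 ± 0.93) and Ilp3 (-3.83 ± 0.99), adjusted p at most 0.00295 (edgeR quasi-likelihood, Benjamini-Hochberg). Among genes above the level minimum set for named genes, the largest contrast was lncRNA:CR40469 (FlyBase FBgn0058469, chromosome X, 122493 to 122706 in dm6), at 10.20 ± 0.30 in young and 9.19 ± 0.29 in old flies. Cyp12d1-d had no count in 26 wild-type libraries and 164 to 553 counts in each ablated library, at least 1650-fold higher against a floor of 3 counts over the wild-type group. Cyp12d1-d has a close tandem copy in the genome, and reads of the copies can be exchanged. Strain background was not separated from ablation in the genotype contrasts, so these values may reflect either. The insecticide-resistance gene Cyp6g1 (FlyBase FBgn0025454, chromosome 2R, 12185667 to 12188431) was higher by 4.74 ± 0.28 in young and 3.82 ± 0.26 in old flies. In young flies these 3 contrasts kept sign and threshold among the 6 libraries of 0 h and 1 h, all of the first set, and in old flies Cyp6g1 did not pass with batch as a covariate, at 2.62 ± 0.76.

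Several lists had members higher in young ablated flies, and none of them passed with the estimated correlation. Rises included Ser6 (3.02 ± 0.19), Jon65Aii (3.52 ± 0.44), Mal-A7 (2.44 ± 0.25), LysE (3.64 ± 0.53), CG3699 (3.84 ± 0.40), Acp65Aa (5.22 ± 1.17) and CG7203 (4.98 ± 0.97), and trypsins and jonahs rose in 15 of 27 cases (camera adjusted p 0.000736 and 0.543). Sugar storage and digestion genes rose in 15 of 17 cases (camera adjusted p 5.65e-08 and 0.137), P450 genes in 19 of 30, with Cyp4p1 (1.90 ± 0.23) (camera adjusted p 2.62e-07 and 0.0898), and glutathione transferases in 9 of 25, with GstE5 (1.14 ± 0.16) (camera adjusted p 0.00238 and 0.137). Oxidative phosphorylation genes rose in 63 of 71 cases, with SdhC (0.84 ± 0.08) (camera adjusted p 1.2e-30 and 0.127), and mt:CoII (0.49 ± 0.07), Ald1 (0.92 ± 0.08), Cat (0.93 ± 0.09), MtnA (1.12 ± 0.15), SREBP (0.56 ± 0.06) and Trap1 (0.78 ± 0.08) rose. Muscle genes rose in 17 of 24 cases, with Mlp60A (0.99 ± 0.10) and TpnC73F (1.27 ± 0.17) (camera adjusted p 1.23e-06 and 0.39), and photoreceptor genes in 15 of 21, with Rh6 (2.03 ± 0.15) and Arr1 (1.11 ± 0.09) (camera adjusted p 7.04e-09 and 0.0898). Ribosomal protein genes rose in 48 of 86 cases, with RpL34b (0.71 ± 0.09) (camera adjusted p 1.67e-07 and 0.543), but their median changed sign to -0.09 with the library set as a covariate and without the 2 doubtful libraries, so no direction was settled. The clock gene per (2.03 ± 0.36) and the stress gene TotX (2.77 ± 0.52) rose. Of 14 alternative fits other than those that left out an hour, the call was kept in 10 for per and Acp65Aa and in 9 for TotX.

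Genes of the eggshell and single genes of other kinds were lower in young ablated flies. The female germline and eggshell list had 10 of 24 members lower (camera adjusted p 0.00019 and 0.272), with Yp3 (-0.89 ± 0.20) and Cp16 (-1.69 ± 0.41), and Femcoat (-1.90 ± 0.45), a gene of the eggshell coat, was lower too. Falls included LysX (-3.39 ± 0.44), CG15721 (-2.40 ± 0.52), CG31928 (-2.33 ± 0.38), Mink (-2.25 ± 0.41), CG31926 (-1.93 ± 0.49), Mtk (-1.53 ± 0.45), CecB (-3.21 ± 0.93) and p23 (-0.74 ± 0.11). Of 14 alternative fits other than those that left out an hour, 10 kept the call of Cp16, Femcoat, Mink and p23. For CG15721 it was kept in 9. CecB lost its call without 4 h (-2.72) or 6 h (-2.63), and the antimicrobial peptide list did not pass, with 1 of 33 higher and 3 lower, 1 up and 2 down adjusted over the list alone (camera adjusted p 0.0908 and 0.795). In the insulin signalling list 9 of 20 genes fell (camera adjusted p 0.000279 and 0.137). That list holds Ilp2, Ilp3 and Ilp5, the transcripts of the ablated cells, so part of its fall follows from the genotype itself. The insulin receptor gene was lower at -0.73 ± 0.28, but it was higher at 0.44 ± 0.11 among the 6 young libraries of 0 h and 1 h, all of the first set. Hsp26 (-0.33 ± 0.13) and Hsp70Ba (-1.76 ± 0.61) were lower as well, but in those 6 libraries they stood at 0.15 ± 0.11 and 0.15 ± 0.32. All 3 genes kept their calls in only 2 of 6 fits that left out an hour. Without 2, 4, 6 or 8 h InR stood at -0.70, -0.65, -0.57 and -0.63, Hsp26 at -0.36, -0.32, -0.23 and -0.31, and Hsp70Ba at -1.52, -1.58, -1.56 and -1.54. The other heat shock genes lay between Hsp70Ab (-1.44 ± 0.60) and Hsp23 (0.81 ± 0.54) without passing. In all, 3779 genes passed, 2081 higher and 1698 lower, but with TMM factors without heat shock genes 1856 were higher and 2033 lower, and with at least 10 counts in 20 libraries 1816 and 2066. Those 6 libraries alone gave 1779 genes, batch as a covariate gave 202, and the library set as a covariate without the 2 doubtful libraries gave 1869, with 847 called in both with the same sign.

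In old flies, with 7 ablated and 13 wild-type libraries, single genes of digestion again stood high in ablated flies. Increases included Jon65Aii (5.36 ± 0.55), CG8329 (5.17 ± 0.42), CG3088 (4.71 ± 0.35), CG8343 (4.07 ± 0.36), Ser6 (2.47 ± 0.19), Mal-A7 (2.91 ± 0.27) and LysE (3.97 ± 0.57), and trypsins and jonahs rose in 21 of 27 cases (camera adjusted p 9.21e-08 and 0.254). The metallothionein MtnB (2.12 ± 0.19), GstD3 (0.91 ± 0.09), SREBP (0.57 ± 0.06), Trap1 (0.97 ± 0.08), Arr2 (1.06 ± 0.09), Pdi (1.20 ± 0.10), Eno (0.66 ± 0.07), SdhB (1.29 ± 0.10) and mt:CoII (0.58 ± 0.07) rose. Ribosomal protein genes rose in 80 of 86 cases, with RpLP2 (0.67 ± 0.06) (camera adjusted p 1.04e-21 and 0.254), and proteasome genes in 24 of 30 (camera adjusted p 2.54e-07 and 0.254). Ilp2 (-5.50 ± 0.80) and Ilp5 (-4.14 ± 0.91) were lower, and Ilp3 (-0.99 ± 0.87) did not pass. With batch as a covariate Ilp2 stood at 0.20 ± 0.41 and did not pass, although it had 5 to 40 counts in each wild-type library and at most 3 in any ablated library. All 7 old ablated libraries were in batch 5, whose only other library was that of ablated young 8 h. In that fit genotype in old flies thus rests on that library and on the additive model, so the fit decides little there. With the library set as a covariate and without the 2 doubtful libraries, Jon65Aii kept 5.00 ± 0.98, CG3088 4.35 ± 0.64 and Ser6 2.03 ± 0.34, with adjusted p of 0.00234, 0.000101 and 0.000165 (edgeR quasi-likelihood, Benjamini-Hochberg). In that fit 16 of 53 named values of this comparison lost their call, LysE, Eno and mt:CoII among them. In old flies the set coincided with genotype. The set term came from the young ablated series and was carried over by the additive model. It therefore cannot separate set from genotype in old flies.

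Falls in old ablated flies took in transcripts without protein coding, the class that separated the library sets. Short and structural transcripts such as sncRNA:254 (-10.14 ± 1.55), snoRNA:Psi28S-3342 (-5.96 ± 0.85), pre-rRNA:CR45845 (-5.91 ± 0.66) and lncRNA:Hsromega (-3.15 ± 0.39) fell, and transcripts of this kind often lie inside other genes, so their counts are uncertain. Coding genes that fell included Kr-h1 (-6.83 ± 0.69), CG45078 (-5.17 ± 0.37), the titin-like gene sls (-3.77 ± 0.35), Tm1 (-1.35 ± 0.09), para (-2.93 ± 0.21), Rdl (-1.96 ± 0.17) and rdgA (-2.17 ± 0.17), and 18 of 21 neuronal genes were lower (camera adjusted p 7.81e-08 and 0.254). Insulin signalling genes fell in 13 of 20 cases, with InR (-3.10 ± 0.30), foxo (-1.97 ± 0.20) and Akt (-1.29 ± 0.13) (camera adjusted p 0.00358 and 0.254), and Atg17 (-1.69 ± 0.16), Mmp2 (-2.68 ± 0.26), Socs36E (-1.89 ± 0.23), the peptide Dso2 (-1.97 ± 0.35) and lncRNA:roX1 (-2.41 ± 0.47) fell. The insulin signalling list includes Ilp2 and Ilp5 of the ablated cells, whose fall follows from the genotype itself. The Hsp70 copies Hsp70Bb (-5.89 ± 0.71), Hsp70Ab (-4.79 ± 0.67) and Hsp70Ba (-4.15 ± 0.70) fell, Hsp83 (0.30 ± 0.07) rose, and the remaining heat shock genes lay between stv (-0.46 ± 0.34) and Hsp70Aa (0.62 ± 0.46) without passing. The copies share reads, and at 0 h Hsp70Bc had 847.8 CPM in old ablated and 396 CPM in old wild-type climbers. With batch or the library set as a covariate, calls were lost for the transcripts without protein coding named here. They were also lost for foxo, Akt, Mmp2, Socs36E, Hsp70Ab, Hsp70Ba and Hsp83. In all, 6515 genes passed, 3419 higher and 3096 lower. With batch as a covariate 199 passed, in a fit where genotype in old flies hung on the ablated young 8 h library. The lower genes prevailed with RLE factors (2986 higher and 3275 lower), in DESeq2 (3092 and 3398) and with TMM factors without heat shock genes (2951 and 3280), so neither direction can be said to lead. The library set as a covariate without the 2 doubtful libraries left 459 genes, 107 higher and 352 lower, with 416 called in both with the same sign.

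Whether the time course itself differed between groups was tested as a slope on the log2 hour in 24 climber libraries. Young ablated flies differed from young wild-type flies in 2027 genes, 766 with a higher and 1261 with a lower slope, and the smallest adjusted p belonged to Mcm10 (-0.89 ± 0.09), cv-c (-1.08 ± 0.12), t (-2.05 ± 0.23), PlexA (-0.70 ± 0.08) and Nop17l (-1.04 ± 0.12). Old and young ablated flies differed in 1435 genes, 1000 higher and 435 lower, led by cv-c (1.01 ± 0.12), Nop17l (0.98 ± 0.12), eIF4B (0.80 ± 0.10), Hipk (0.63 ± 0.08) and retm (0.62 ± 0.08). Both counts were 0 with the library set as a covariate, where the young ablated series crossed from the first set to the second between 1 h and 2 h. The first count was 706 without the 0 h libraries, 1222 without 1 h and 1083 without 6 h, and the second was 210 without 0 h, 788 without 1 h, 609 without 6 h and 946 without 8 h. In the slopes the inducible heat shock list had 5 of 16 members lower in young ablated against young wild-type flies (median -0.36) and 3 higher in old against young ablated flies (median 0.27). In the other 3 slope comparisons it had none.

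The other slopes gave few or no genes. Old and young wild-type flies differed in no gene in edgeR quasi-likelihood (403 at an unadjusted p under 0.05, 17 in DESeq2 and 0 in limma-voom), and the smallest p belonged to CG34136 (-0.63 ± 0.12), Srp68 (0.23 ± 0.05) and CG9393 (0.29 ± 0.07), which did not pass. Old ablated and old wild-type flies differed in none (685 at an unadjusted p under 0.05, 34 in DESeq2, 1 in limma-voom), and Ilp8 (0.65 ± 0.10), CG15406 (0.69 ± 0.13) and kumpel (0.62 ± 0.13) had the smallest p without passing. Non-climbers and climbers differed in slope in 3 genes of 24 wild-type libraries, lncRNA:CR45408 (6.80 ± 1.01), CG15784 (0.24 ± 0.05) and CG12826 (0.79 ± 0.15), each at an adjusted p of 0.0438 (edgeR quasi-likelihood, Benjamini-Hochberg). Of these 3, none passed with batch as a covariate or in limma-voom, and lncRNA:CR45408 had no count in most libraries. Of 6 fits that left out an hour, the call was kept in 3 for lncRNA:CR45408, 2 for CG12826 and 1 for CG15784.

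The split between higher and lower genes also depended on the fit. With RLE factors 32% of the 3859 genes of the age comparison in ablated flies were higher against 42.5% with TMM, and 27% of the 1838 slopes between ablated and wild-type young flies against 37.8%. At 6 h the only gene left with RLE factors was higher, against 84.6% of 13 genes. With DESeq2 58.5% of the genes at 8 h were higher against 45.7%, and 55% of the 20 slopes between behaviour classes against 100%. Batch as a covariate moved the share from 50.2% to 67.1% for age in wild type, from 55.1% to 76.7% for genotype in young flies, from 37.8% to 4.64% and from 69.7% to 90.2% for the slopes in young flies and in ablated flies, and from 45.7% to 61.1% at 8 h. In limma-voom it fell from 72.6% to 48.9% at 2 h and from 84.6% to 55.6% at 6 h. At 1 h the share of 47% moved both ways, to 34.4% in limma-voom, but to 61% without a count filter, 55.5% with at least 10 counts in 20 libraries, 54.9% with RLE factors and 54% with TMM factors without heat shock genes. The median over all genes in old ablated flies shifted by 0.106 with batch as a covariate, by -0.105 with the library set as a covariate, and by -0.103 when the 2 doubtful libraries were left out as well.

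For some lists the median and the direction of the camera test differed in sign, and none of these tests passed. In the heat contrasts this held at 0 h for insulin signalling, antioxidant genes and trypsins, at 1 h for the Turandot list, at 2 h for proteasome, trypsins and neuron, at 4 h for Turandot, male and oxidative phosphorylation, and at 6 h for constitutive chaperones and lipids. Between 8 h and 0 h it held for insulin signalling, clock, neuron and photoreceptor. Between behaviour classes it held for insulin signalling, FOXO-activated genes, antimicrobial peptides, glutathione transferases and clock over both ages. It held for insulin signalling, glutathione transferases and clock in young flies, for constitutive chaperones, insulin signalling, FOXO-activated genes and haemocytes in old flies, and for the proteasome in the difference between ages. With age it held for autophagy in wild type and for Turandot and lipids in ablated flies. With ablation it held for inducible heat shock, proteasome, FOXO-activated genes and male genes in young flies, and for inducible heat shock and haemocytes in old flies. Constitutive chaperones in the interaction of age and genotype had a median of 0.18 and a mean of -0.07, and their test passed at a camera adjusted p of 0.0479. Other differences in sign between median and mean were in lists whose test did not pass.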

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

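The tests of library depth and of a weak response for the oddly labelled libraries, all tests of the library sets and the test of the hour of collection were chosen only after the results were seen. Several results stood apart because groups differed from each other in their time course or in their response to age.

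The age effect differed between genotypes in 4162 genes, led by CG5065 (-1.75), eEF1alpha2 (-1.70), Cngl (-2.19), Moe (-1.35) and cpo (-1.80), log2 values of ablated minus wild type. The slope over recovery differed between old and young ablated flies in 1435 genes, led by cv-c (1.01), Nop17l (0.98), eIF4B (0.80), Hipk (0.63) and retm (0.62). Between ablated and wild-type young flies it differed in 2027 genes, led by Mcm10 (-0.89), cv-c (-1.08), t (-2.05), PlexA (-0.70) and Nop17l (-1.04). These slopes rest on the young ablated series, which crosses from the first library set to the second between 1 h and 2 h, and both counts were 0 with the set as a covariate. Between non-climbers and climbers the slope differed in 3 genes, named after their values were seen, lncRNA:CR45408 (6.80), CG15784 (0.24) and CG12826 (0.79), and in 0 genes with batch as a covariate.

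The library labelled ablated young control carried more heat shock transcript than the other controls, and the library labelled ablated young 6 h carried as little as a control. Library depth was excluded, because both libraries had nearly equal totals and their indices still differed by 2.13 on the log2 scale. A response of young ablated flies as low as the other controls was excluded as well, because the lower of their 4 h and 8 h indices lay 1.02 above the highest of those controls. That test used the controls of other strata. It cannot exclude a weak response on a raised baseline, since the labelled control stood at 5.66 and the 8 h library at 5.75. The labelled 6 h library, at 3.53, lay below both. An exchange of the labels may explain both libraries, since the labelled 6 h minus control difference ran against the 6 h effect of the other strata over 421 genes outside the heat shock list (Spearman correlation -0.75 across genes, which are not independent replicates), while each of the other strata, from which that effect was computed, gave 0.95. The labels were kept, and an exchange before or after library preparation was not distinguished.

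The libraries formed 2 sets, of 28 and 12, in their transcripts without protein coding. The labelled batch was excluded as the cause, since the sets were 21.6 apart inside batch 4, and so was ablation or strain background as the whole cause, since 2 ablated libraries without an Ilp2 count lay with the wild-type libraries. Library depth was excluded because 9 libraries of the second set had totals inside the range of the first. An unrecorded preparation or sequencing step could not be excluded, with a median snoRNA difference of -0.81 within the young ablated series (SD 1.14 over 117 genes) against -0.03 in the same hours of young wild-type climbers. That step and the ablated genotype cannot be told apart in the 12 libraries of the second set, since no wild-type library belongs to it.

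Vitelline membrane and eggshell transcripts fell between 0 h and 8 h. The labelled batch was excluded, because the median of the 4 vitelline membrane members was -4.09 with batch as a covariate (median SE 1.01, 3 of 4 past the threshold) and -3.56 without it. An even loss of ovary in the 8 h libraries was argued against by 7 germline members. They had a median of -0.23 and ranged from -0.60 to 0.15, with 1 past the threshold. These are germline transcripts, so a loss of the follicle cells that transcribe vitelline membrane genes was not excluded. The hour of collection alone could not be excluded, because controls were taken only at 4 h, so no test at that hour could decide it for 8 h. At 4 h climbers lay -0.79 from the control of that hour in 3 strata (SD 0.31). The difference was 0.47 in young ablated flies, whose control is in doubt, and -0.47 over all 4 (SD 0.68). The stage of the eggs and the feeding of the flies were not tested, so the cause stays open.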

How the results depend on the processing

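The fits with the library set as a covariate, those without up to 4 ablated young libraries, and those on the 6 young libraries of 0 h and 1 h or on the ablated libraries of 2, 4 and 8 h were chosen only after the results were seen. Counts are genes with an adjusted p under 0.05, and most of those given below moved by more than 1.5 times, while for fits that left out 1 hour or 1 control the lowest and the highest count are given whether or not they moved that far. The cause was not tested unless it follows from how a fit was built.

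DESeq2 called more genes than edgeR in the sparse comparisons. It gave 777 against 443 at 0 h, 450 against 234 at 1 h, 354 against 157 at 2 h, 269 against 88 at 4 h, 101 against 13 at 6 h and 212 against 81 at 8 h, each against the controls. Where edgeR called none, DESeq2 called 3 genes between non-climbers and climbers, 2 in young flies, 1 in old flies and 4 for the difference between ages. It called 17 slopes between old and young wild-type flies and 34 between ablated and wild-type old flies, and for the slope between behaviour classes it called 20 against 3. Of 327 values of named genes, 313 kept their call and 14 gained one.

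Scaling and filters moved few counts this far. RLE factors gave 1 gene at 6 h, and 323 of 327 named values kept their call. Leaving the inducible heat shock genes out of the TMM factors changed the call of none of the 327. Without a count filter 56 genes passed at 4 h, 1 at 6 h and 52 at 8 h, while 1 gene passed for the slope between ablated and wild-type old flies and 6 for that between behaviour classes. At least 10 counts in 20 libraries gave 0 for the slope between behaviour classes.

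Batch as a covariate changed most of the group comparisons. The batches follow genotype and age, but this fit also tested 12876 genes against 11449, since the count filter depends on the model, and the effects of these changes were not separated. Age in wild type went from 2692 genes to 79, age in ablated flies from 4241 to 973, genotype in young flies from 3779 to 202, genotype in old flies from 6515 to 199, and the interaction of age and genotype from 4162 to 286. The test over the 6 hours went from 997 to 384 and the 8 h against 0 h contrast from 1201 to 306, whereas 4 h against control rose to 226 and 6 h to 28. The slope between ablated and wild-type young flies fell to 431, that in old flies gave 1, and that between behaviour classes gave 0. Of 327 named values 186 kept their call, 139 lost it, and a pair reversed in sign. These were Hsp26 in young ablated flies, at 0.03 ± 0.35 against -0.33 ± 0.13, and Ilp2 in old ablated flies, at 0.20 ± 0.41 against -5.50 ± 0.80. The old ablated libraries shared their batch only with ablated young 8 h. Their contrasts in this fit thus rest on that library and the additive model, and lost calls there say little about the effects. Limma-voom with batch as a random block gave 686 at 0 h, 352 at 1 h, 305 at 2 h and 36 at 8 h, with 1 gene for the slope between ablated and wild-type old flies and 0 for that between behaviour classes.

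Leaving out the libraries labelled ablated young control and ablated young 6 h raised the late heat counts to 297 at 2 h, 379 at 4 h, 432 at 6 h and 527 at 8 h. Without the ablated young 0 h and 1 h libraries the counts were 121 at 1 h, 279 at 2 h, 223 at 4 h, 7 at 6 h and 137 at 8 h. The slopes then fell to 46 between old and young ablated flies and 85 between ablated and wild-type young flies, and 1 gene passed between ablated and wild-type old flies. Without all 4 libraries the counts were 519 at 2 h, 644 at 4 h, 644 at 6 h and 767 at 8 h, age in ablated flies gave 2048 and the interaction 2615. The slopes in that fit gave 37 between old and young ablated flies, 66 between ablated and wild-type young flies and 1 between ablated and wild-type old flies.

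The library set as a covariate, with 11873 genes tested, gave 273 genes at 2 h, 218 at 4 h and 139 at 8 h. Genotype gave 1727 genes in young and 510 in old flies, and the slopes between old and young ablated flies and between ablated and wild-type young flies both gave 0. The set changes within the young ablated series, so the set term and the slope share part of their course there. The slopes could still be estimated, and whether set or hour accounts for the lost calls was not tested. Hsp70Ba between old and young ablated flies turned to 0.01 ± 0.27 from -1.95 ± 0.69, Hsp26 in young ablated flies to 0.02 ± 0.19, and InR in young ablated flies to 0.56 ± 0.19 from -0.73 ± 0.28 with an adjusted p of 0.0469 (edgeR quasi-likelihood, Benjamini-Hochberg).

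With the same covariate and without the libraries labelled ablated young control and 6 h, the counts were 521 at 2 h, 630 at 4 h, 610 at 6 h and 736 at 8 h. Age in ablated flies gave 2111, genotype 1869 in young and 459 in old flies, the interaction 2597, and the same pair of slopes 0. Hsp26 was 0.01 ± 0.18 and InR 0.56 ± 0.19, with an adjusted p of 0.0405 for InR (edgeR quasi-likelihood, Benjamini-Hochberg). The ribosomal protein list in young ablated flies turned downward with an adjusted p of 0.000708 with the preset correlation but 0.583 with the estimated correlation, and oxidative phosphorylation in old ablated flies turned downward without passing at 0.981 with the preset correlation (camera). Of 324 named values 274 kept their call.

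Smaller sets of libraries gave other counts. The 10 libraries of 4 h gave 169 genes, and the pair as a block gave 2 genes between behaviour classes and 2 in old flies. The 12 climbers of both strata gave 1786 for age in ablated flies and 1316 for genotype in young flies. The ablated libraries of 2, 4 and 8 h gave 752 for age. The 6 young libraries of 0 h and 1 h gave 1779 for genotype, with Hsp70Ba at 0.15 ± 0.32 against -1.76 ± 0.61, Hsp26 at 0.15 ± 0.11 and InR at 0.44 ± 0.11. A slope on hours gave 952 between old and young ablated flies. Of the tests of lists, 171 passed with the preset correlation of camera and 17 with the estimated correlation, while fry gave 123.

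Leaving out 1 time point or 1 control moved the following results. Without the ablated old control 294 genes passed at 0 h, and without the 1 h libraries 530. At 1 h the count ran from 128 without the wild-type young control to 330 without the 8 h libraries, and at 2 h from 78 without the ablated old control to 243 without the labelled ablated young control. At 4 h it ran from 5 without the wild-type young control to 277 without the labelled ablated young control. At 6 h it ran from 0 without the 1 h libraries to 107, and at 8 h from 0 without the wild-type young control to 465, both highest without the labelled ablated young control. The test over hours gave 495 without 0 h and 925 without 4 h. Between behaviour classes 0 genes passed without 1 h and 1 without 0 h. The slope between old and young ablated flies ran from 210 without 0 h to 1478 without 2 h, and that between ablated and wild-type young flies from 706 without 0 h to 1803 without 2 h. In wild type the age slope gave 0 without 1 h and 1 without 0 h, the old genotype slope 0 without 2 h and 3 without 0 h, and the slope between behaviour classes 1 without 0 h and 5 without 6 h. The cause of these shifts was not tested.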

Other observations

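The tests on old non-climbers and on all 12 pairs were chosen only after the result was seen, whereas that on young non-climbers and the counts of other splits were planned. Non-climbers may carry more heat shock transcript than climbers of the same hour. In old flies the index was higher in 5 of 6 pairs, by 0.38 on average (SD 0.40), with an exact two-sided sign-flip p of 0.0938. The largest difference, 0.89, was that of the 1 h pair, the only pair that joins 2 batches, and its climber is the library with high Act88F described below. In young flies it was higher in 5 of 6 pairs, by 0.18 (SD 0.16), with an exact sign-flip p of 0.0625. Neither reached 0.05 alone. Over all 12 pairs the index was higher in 10, by 0.28 (SD 0.31), with an exact sign-flip p of 0.00293, and without the old 1 h pair by 0.23 (SD 0.25), with a p of 0.00586. The pairs together thus lean as the hypothesis needs, but it was found on these data and stays a hypothesis.

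The libraries were regrouped within matched pairs or within a series of hours, each split and its mirror being taken once, and the genes passing in limma-voom were counted. There were 100 splits, or fewer where the pairs allow no more. For the heat contrasts 1 of the 100 splits, the real split itself, gave as many genes at 0 h (687 genes, highest other 22), 1 h (334 and 100), 2 h (297 and 14), 4 h (100 and 3) and 8 h (69 and 28). These splits exchanged all hours and the control of a series together. They thus test for any effect of heat or hour, and chance was not excluded for a single hour. At 6 h the real split gave 9 genes and the highest other 52, and 4 of 100 splits gave as many, just under the planned limit. Chance was not excluded at that hour. That other split called several times the real count, which points to structure among the libraries. Chance could be excluded for the test over hours (1360 and 26). The count for 8 h against 0 h (1506 and 17) stood alone too, under the same limit as the single hours.

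For age and genotype the real split again stood alone. It gave 2802 genes for age in wild type (highest other 1881), 4653 for age in ablated flies (2583), 4240 for the interaction (2368), 4416 for genotype in young flies (2369) and 6813 for genotype in old flies (4455). Chance could be excluded for age and for genotype. Only the real split was as large, of 64 for age in ablated flies and for genotype and of 100 for age in wild type. For the interaction it was also the only 1 of 100, but these splits exchanged old and young in both genotypes. They thus test for any effect of age, and chance was not excluded for a difference between genotypes. The highest other splits of those 64 moved only 2 libraries, a single pair, and so stayed close to the real split. Those for age in wild type and for the interaction moved 8 and 20 libraries. That number does not tell how much of the real contrast stayed in these splits. Whether closeness to the real split or structure among the libraries gave their counts was not examined. Excluding chance does not separate genotype or age from batch or library set.

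For behaviour the splits say nothing about chance, because any split has at least 0 genes. The real split gave 0 genes over both ages (highest other 3), 0 in young flies (0), 0 in old flies (3) and 0 for the difference between ages (11). All 32 splits within an age and all 100 of the others therefore gave as many. For the slopes 2 of 100 splits gave as many genes between old and young ablated flies (1413 genes, highest other 1585). Between ablated and wild-type young flies only the real split did (2287 and 1263). These splits exchanged all hours of a series, so they exclude chance only for an effect of hour of any kind. In the highest other split of each, the first libraries of the young ablated series kept their hours of 0 h and 1 h, so that the library set still followed the hour. Chance could not be excluded for the slope of genotype in old flies (1 and 7, 11 of 100 splits as large). The slope of age in wild type (0 and 4) and that between behaviour classes (0 and 2) gave no gene in the real split, so all 100 splits gave as many and nothing follows about chance.

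Single libraries carried signals of other kinds. The young wild-type non-climber library of 6 h had 15.6 CPM of SP and 3.46 CPM of Acp26Aa, transcripts of the male accessory gland, where the highest values of the other libraries were 0.399 and 0.188. The old wild-type climber library of 1 h had 639 CPM of the flight muscle gene Act88F, against 33.8 to 83.6 in the other old libraries. The source of these signals was not tested.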
